A study of Enchytraeus crypticus with 24 samples.

How the data were processed

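Whole-body RNA of 40 adult worms per sample was measured on custom one-colour arrays, 1 array per sample. Per the labels' protocols, each sample's RNA (500 ng) was amplified with a single dye, and spike-in RNA was added as a positive control. The scanner files were made with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, per the file headers. They hold the deposited intensity of each spot as a processed signal, which that software had background-subtracted with spatial detrending and replaced near 0 by surrogates per the file headers, beside median spot and background intensities and flags of 0 or 1 per spot, the last kept here as other values. Values were not normalized between arrays. The series-wide table of the authors' processed values was set against the processed signal of each scanner file and was identical on all 24 arrays (largest difference 0), on a linear scale, without centring. What the authors did after that step is not given in the sources used here.

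Control spots were left out. Spots marked as non-uniform or as population outliers, at most 31 on an array, were set missing. From each log2 processed signal the array's 75th percentile was subtracted. Since at most 43.6% of the probes were detected on an array, the percentile was taken over the 7428 probes well above background on all 24 arrays. Probes well above background on all 3 arrays of at least 1 group were tested, 15565 of 43750. Groups were taken from the labels, which give dose, day and replicate number. The 24 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 1 mean for each of the 8 groups, so that all groups share an estimate of the spread, and moderated with eBayes. Contrasts were each dose against the control of the same day, any dose against control and differences among the 3 doses (F-tests), day 21 against day 2 in controls, and the difference of each dose's change between the days. P-values were adjusted by Benjamini-Hochberg within a contrast, and a probe is called at an adjusted p under 0.05. Levels are log2 signals relative to the 75th percentile, so a change is relative to the bulk of probes on the array, and any loss or gain of all messenger RNA is removed. Median signals of the probes above background lay between 46.9 and 186 intensity units per array.

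Where a probe was not well above background on any array of a group, the fold is given as a bound. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among probes well above background. The bound thus applies to the group means. It leaves out the spread of the brighter group and is not a confidence limit. Shared controls were simulated with 100 draws of unchanged groups. Correlations across probes use probes that are not independent. Choices of contrasts, tests, filters and alternatives were made before the data were examined, unless stated otherwise. The fixed rule allowed at most 2 probes that rose and 2 that fell to be named where probes carry no annotation. Taken were the probes of largest change over the 6 exposure contrasts among called probes whose 3 exposed arrays all lie on one side of the 3 controls. The 25 gene lists fixed beforehand, the set tests on them and the tissue markers among them need gene names, which the probes do not carry in the files, so they are not analysed here.

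Arrays came from 12 slides and 4 scan sessions. The round of an array was read from the spike-in probes n9 and n11, after the data were seen, and coincides with scan session 2 against the other 3. Round and scan session were each fitted as a block beside the groups, and the contrasts were fitted again within each round or session that held both groups. No slide held a control and an exposed array of the same day, so no value within a slide can be given. With slide as a fixed block, 5 residual degrees of freedom were left, and limma called 3 probes in each of the day-2 tests over several doses and 0 in the other 12 contrasts. At an unadjusted p under 0.05 those 12 had between 225 and 2154 probes.

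The groups share replicate numbers 1, 2 and 3 in the labels, which do not say what a number stands for. The choice was made from correlations of arrays and not from calls. Deviations of arrays from their group means were correlated over 7401 probes. For replicates 1, 2 and 3, the correlation of day-21 control and exposed arrays was 0.58, 0.34 and 0.78 at 100 mg/kg, 0.57, 0.25 and 0.67 at 500 mg/kg, and 0.49, 0.22 and 0.57 at 1000 mg/kg. All lay above 0.1, and all 6 arrays of each of these contrasts correlated best with their own number, so the numbers were taken to pair the day-21 arrays, and the fit with the number as a block is given beside those results within day 21 that it moves by over 1.5 times. Within groups, arrays correlated at 0.821 or more over probes.

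The steps were tested on simulated data for the contrast of 1000 mg/kg on day 21, with 15507 probes, 200 of them changed, and 20 draws. With independent noise, 4.35% of 2-fold and 39.4% of 4-fold changes were called, with a median of 2 false calls. With the noise of whole arrays drawn from the measured residuals, 5.00% and 37.6% were called, the false calls reached 502 in the changed contrast, and up to 2922 probes were called in an unchanged one. No changed probe was called with the wrong sign in either case.

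Alternatives were quantile normalization, scaling by the median, no filter and a strict filter on dim probes (well above background on all 24 arrays), the series-wide values, fits of only the arrays compared, a replicate, slide or scan session block, array weights, a trended and robust prior, a 2-fold minimum, and leaving out each array. Added after seeing the data were normexp (offset 50) on the median spot signals with quantile normalization, the 75th percentile over all probes, scaling by 4 spike-in probes, slide as a random block, round as a block with and without the replicate number, fits without the 4 arrays of widest negative controls, and fits within a round or session. Simulated lists of the 5 and 42 probes of smallest p in unchanged groups, and medians with dim groups at their bound, were also added then.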

Results

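Gene expression was measured in Enchytraeus crypticus, a small soil-dwelling oligochaete worm (a potworm) used in soil ecotoxicology, after exposure to WELGRO, a commercial nano-enabled fertilizer. Adult worms were kept for 2 or 21 days in un-spiked soil or in soil with 100, 500 or 1000 mg of WELGRO per kg. Each of the 8 combinations of dose and day was measured on 3 one-colour arrays, which the study calls biological replicates, so 24 arrays were compared, each holding RNA from 40 pooled worms. An array carried 43750 probes, of which 23177 were designed on assembled contigs of expressed sequence and 20573 on single sequencing reads. The files pair the probes with these sequence names and with no gene name, so changes are described here by probe, and no genome position is given. Between 24.2% and 43.6% of the probes were well above background on an array, no probe was saturated, and 15565 probes were well above background on all 3 arrays of at least 1 group and were tested. The number of arrays limits the precision of every value.

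The arrays fell into sets that overlap with the days but that doses and days do not fully explain. The difference between a pair of spike-in control probes (log2 signal of n9 minus that of n11), which do not measure worm RNA, lay between 0.70 and 1.45 on 13 arrays and between -2.67 and -1.67 on the other 11. These sets are called rounds A and B below, and round A was scanned in 1 of the 4 scan sessions and round B in the others. All 9 exposed arrays of day 21 belonged to round A, against 1 of the 3 day-21 controls, replicate 1. Without that control, any day-21 contrast with control sets round A against round B. On day 2, round A held 1 control array and 2 of the arrays at 500 mg/kg, and every array at 100 and 1000 mg/kg belonged to round B. The first principal component of the 7401 probes measured and well above background on all arrays held 41.0% of the variance. Round explained 78.1% of that component, day 51.3% and dose 10.6%. Since round and day overlap, these shares overlap too and cannot be added. In a limma fit with round beside the 8 groups, 3987 probes differed between the rounds, 2942 of them higher in round A. Negative control spots spread most on 4 arrays, with SDs between 3.86 and 5.72 against 1.52 to 2.35 on the others. These were day-2 control replicate 3, day-21 control replicates 1 and 3, and replicate 1 at 100 mg/kg on day 21.

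**Figure D1:**
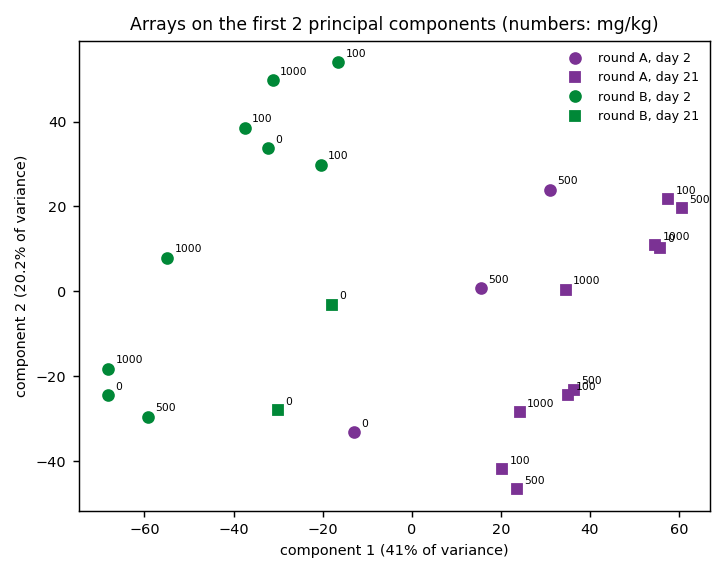
Scores of the 24 arrays on the first 2 principal components, which held 41.0% and 20.2% of the variance (axes in units of log2 signal summed over probes). Colour marks the round, circles day 2, squares day 21, and the small numbers give the dose in mg/kg. Every array of round A lies to the right of every array of round B.

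With all arrays in one fit, the highest dose on day 21 gave the most changes among the exposures. This order depends on the setting, as the following and other settings show. With scan session as a block 151 probes passed at 1000 mg/kg on day 2 against 21 on day 21. With array weights, whose estimation stopped before converging, 3357 passed at 500 mg/kg on day 2 against 1330 at 1000 mg/kg on day 21. Without day-21 control replicate 1 there were 1578 at 500 mg/kg on day 21 against 1204, both in contrasts of round A with round B. Without the 4 arrays of widest negative controls, only replicate 2 of the day-21 controls is left, so that setting is not used for the order. Without day-2 control replicate 1 the count at 100 mg/kg on day 2 was 737, and without day-2 control replicate 3 that at 500 mg/kg was 241. In the fit of all arrays at 1000 mg/kg, 42 of the 15565 probes differed from the day-21 control, 28 of them higher and 14 lower, with a median fitted size of 2.73 on the log2 scale, or 2.31 with groups not well above background at their bound. The balance of directions was not stable, with 56 higher and 91 lower without exposed replicate 1, 29 and 28 without control replicate 2, 5 and 7 within round A, and 88 and 1530 with no filter on dim probes. The largest fitted rise was that of GYUW2K401DLQ92, a probe on a single read. Its level on the log2 scale was 1.54 ± 1.49 (SD, n = 3) at 1000 mg/kg, and it was not well above background on any of the 3 controls, so its mean was at least 195-fold higher (7.61 on the log2 scale at the bound, 8.99 as fitted, SE 0.72, limma adjusted p = 2.36e-06). Probe contig17562 rose from -4.68 ± 1.84 to 4.01 ± 0.33 (SD, n = 3 each), a log2 fold change of 8.70 (SE 1.01, adjusted p = 0.000219). Probe contig14152 fell the most, from -0.92 ± 1.41 to -7.30 ± 1.46 (SD, n = 3 each), a log2 fold change of -6.39 (SE 1.10, adjusted p = 0.0109), and was well above background on 1 of the 3 exposed arrays. Without exposed replicate 2 or 3 it did not pass (log2 fold change -6.12 and -5.83, adjusted p = 0.0923 and 0.0836), nor did it with scan session as a block (-7.07, 0.0521), within round A (-6.82, 0.197) or with normexp (-2.95, 0.122). Probe contig17562 did not pass within round A (log2 fold change 6.58, adjusted p = 0.102). None of these 3 probes passed in a fit of only the arrays compared (adjusted p = 0.0923 for GYUW2K401DLQ92, 0.113 for contig17562 and 0.235 for contig14152) or with slide as a fixed block (1 for each). Over all settings the adjusted p ran from 4.28e-07, 2.03e-05 and 0.000385 to 1.

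Of the 42 probes, 9 were not well above background on any control array, 5 were not so on any exposed array, 1 of them in neither group, and 15 were above it on all 24 arrays. They lay on 23 contigs and 19 single reads. With the replicate number as a block, 80 probes passed, 48 higher and 32 lower, including all 42. A block of round left 33, including 25 of the 42. Within round A, where 3 exposed arrays met 1 control, 12 passed, and with scan session as a block 21 passed. Round B held no exposed array of that day. Fitting only the 6 arrays compared left 0 calls. Leaving out control replicate 1 gave 1204 calls, but it is the only round-A control of the day, so that fit compares round A with round B. Leaving out 1 other array gave 147 calls without exposed replicate 1, and 16, 20 and 18 without exposed replicates 2 and 3 and control replicate 3.

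In most of the 42 probes the 500 mg/kg group lay further than the 100 mg/kg group in the direction of the 1000 mg/kg change, but this was also so in some draws of unchanged groups. The median fitted log2 change, signed by the direction at 1000 mg/kg, was 0.29 at 100 mg/kg, 1.58 at 500 mg/kg and 2.73 at 1000 mg/kg (0.29, 1.42 and 2.31 with dim groups at their bound). For the 42 probes of smallest p in unchanged groups simulated against shared controls, the means over 100 draws were 0.81, 0.79 and 1.67. The sign at 1000 mg/kg was shared by 39 of the 42 at 500 mg/kg and by 34 at 100 mg/kg, against 37.3 and 38 in the simulation. In 28 probes the level rose from 100 through 500 to 1000 mg/kg, in 11 it fell in that order, and 3 were highest or lowest at 500 mg/kg. The 500 mg/kg group lay further in the direction of the 1000 mg/kg change than the 100 mg/kg group in 39 probes (92.9%), against 57.0% of all tested probes and a simulated mean of 48.5%, and 6 of the 100 draws reached 92.9%. All 3 groups were measured in round A. The share was 57.1% among the probes called without replicate 1 at 1000 mg/kg, 76.2% and 66.7% without control replicates 1 and 2, 62.0% with array weights, 62.7% without the 4 arrays of widest negative controls and 66.7% within round A.

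**Figure D2:**
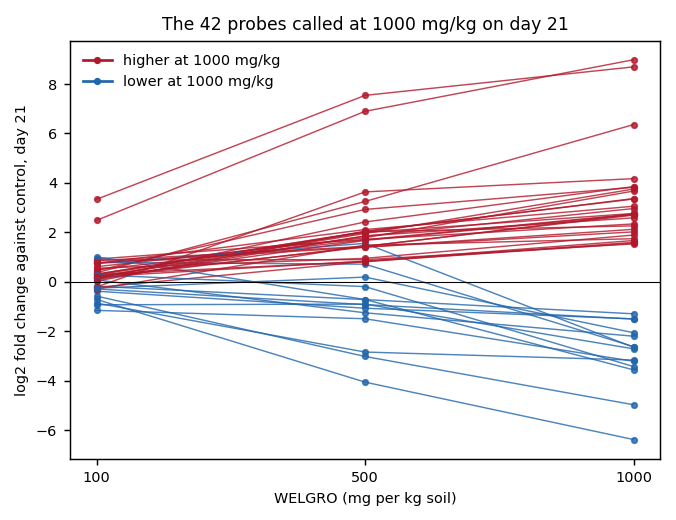
Log2 fold change against the day-21 control at each dose (equally spaced on the x axis, mg per kg soil) for the 42 probes called at 1000 mg/kg. Each line is a probe, red for the 28 higher and blue for the 14 lower, and in 39 of them the value at 500 mg/kg differs from that at 100 mg/kg in the direction of the change at 1000 mg/kg.

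At 500 mg/kg on day 21, 5 probes differed from the control, 4 higher and 1 lower, and all 5 were among the 42 changed at 1000 mg/kg in the same directions. Probe contig17562 rose by a log2 fold change of 7.54 (SE 1.01, adjusted p = 0.00365), to a level of 2.86 ± 1.34 (SD, n = 3). Its controls lay at -2.57 in round A and at -5.65 and -5.84 in round B, and the exposed arrays were all of round A. Part of the fitted rise may thus be a difference of round. Probe GYUW2K401DLQ92 reached -0.55 ± 1.04 (SD, n = 3), at least 45.9-fold above the control (5.52 on the log2 scale at the bound, 6.90 as fitted, adjusted p = 0.000184). Probe contig14152 had a log2 fold change of -4.06 (SE 1.10) that did not pass (adjusted p = 0.304). For 5 and 42 calls, independent lists would share 0.0072 higher and 0.000899 lower probes. In unchanged groups simulated against shared controls, the 5 and 42 probes of smallest p shared 0.96 in the same direction on average (95% of draws between 0 and 4), and 1 of 100 draws shared 5. Part of the overlap may come from the shared control arrays, since 3 arrays cannot be split into equal parts. A block of round left 3 probes, of which 2 were among the 5, with scan session as a block 2 passed, and within round A 2 passed. Leaving out 1 array gave 1578 calls without control replicate 1 (a contrast of round A with round B), 3 without control replicate 3, and 1, 3 and 3 without exposed replicates 1, 2 and 3.

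At 100 mg/kg on day 21 no probe passed. The count of 0 in limma stands beside 1179 probes (7.57%) with an unadjusted p under 0.05 and a smallest adjusted p of 0.633. The mean of probe GYUW2K401DLQ92 was at least 2.15-fold above that of the control (2.48 on the log2 scale as fitted, SE 0.72), and contig17562 had a log2 fold change of 3.34 (SE 1.01). Neither change passed in limma, both with an adjusted p of 0.633. The exposed arrays of contig17562, all of round A, lay at -0.49, -0.45 and -3.11. Its controls lay at -2.57 in round A and at -5.65 and -5.84 in round B, so part of its fitted change may be a difference of round. The count stayed at 0 with round, scan session or replicate number as a block and within round A, where 309 probes had an unadjusted p under 0.05. Without control replicate 1 it was 745, in a contrast of round A with round B.

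**Figure D3:**
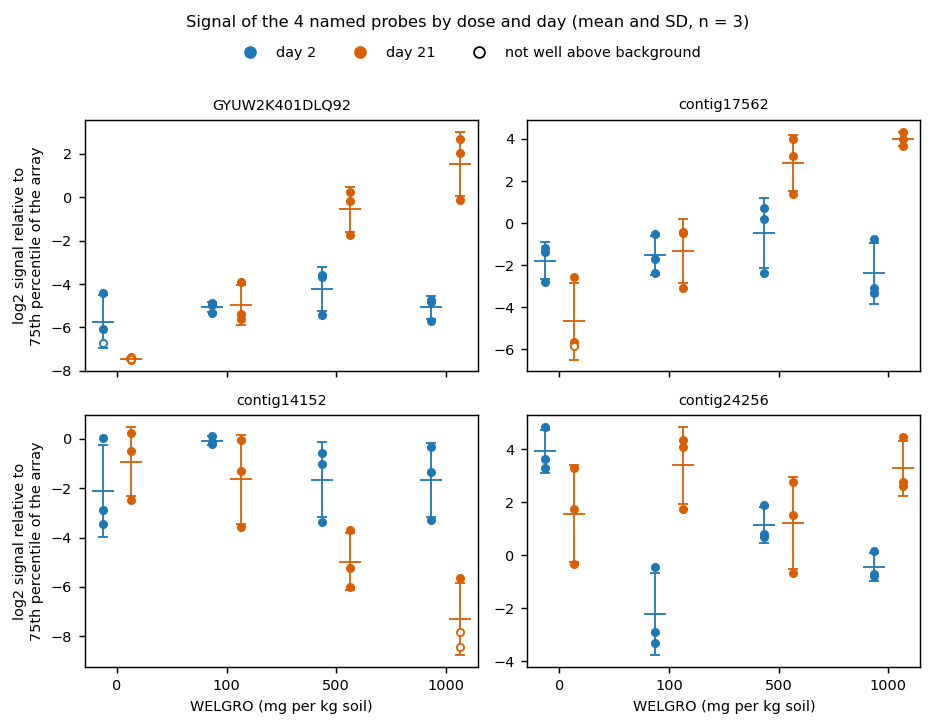
Log2 signal relative to the array's 75th percentile (y axis) of the 4 named probes by dose (x axis, mg per kg soil), with blue for day 2 and orange for day 21. Points are arrays, open where the probe was not well above background, and bars give the mean and SD of 3 arrays. On day 21 GYUW2K401DLQ92 was not well above background in controls and had a mean of 1.54 at 1000 mg/kg, and contig14152 went from -0.92 to -7.30.

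The tests over all 3 doses on day 21 gave 36 probes that differed from control in any exposure and 40 that differed among the doses. Of the 36, 16 had a higher mean and 5 a lower mean in all 3 doses, and 28 were also called at a single dose. The means compared among the doses hold no control array and only arrays of round A, while the spread in that test comes from all 24 arrays. Of its 40 probes, 18 rose and 6 fell from 100 through 500 to 1000 mg/kg, 16 had their highest or lowest level at 500 mg/kg, and 22 were among the 42 called at 1000 mg/kg against control. GYUW2K401DLQ92 (adjusted p = 0.00169) and contig17562 (adjusted p = 0.0457) were among the 40, and contig14152 was not (adjusted p = 0.0691). With the replicate number as a block, the counts were 65 for any exposure and 62 among the doses, with round as a block 41 and 60, with scan session as a block 61 and 74, and within round A 24 and 38. Fits of only the day-21 arrays gave 21 and 12. For any exposure, the count was 480 without control replicate 1 (a contrast of round A with round B), 57 without control replicate 2, and 141 and 23 without replicates 1 and 2 at 1000 mg/kg. For the differences among the doses it was 195, 16 and 18 without replicates 1, 2 and 3 at 1000 mg/kg, 26, 22 and 25 without replicates 1, 2 and 3 at 500 mg/kg, and 22 and 19 without replicates 1 and 3 at 100 mg/kg.

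After 2 days few probes passed at any dose in the fit of all arrays without a block, and other settings moved these counts. At 100 mg/kg 3 probes differed from the day-2 control, 2 higher and 1 lower. The lower one, contig24256, went from 3.91 ± 0.82 in controls to -2.22 ± 1.54 (SD, n = 3 each), a log2 fold change of -6.14 (SE 0.98, limma adjusted p = 0.0390). It passed without control replicate 1 or exposed replicate 3 and not without any one of the other 4 arrays, where the adjusted p lay between 0.136 and 0.195 and the log2 fold change between -6.45 and -5.59. Nor did it pass within round B (log2 fold change -5.67, adjusted p = 0.351), with spike-in scaling (-5.39, 0.29), with slide as a random block (-6.45, 0.056) or a fixed one (-7.36, 0.35), with no filter (-6.14, 0.0521), without the 4 arrays of widest negative controls (-5.67, 0.164) or in a fit of only the arrays compared (-6.14, 0.235), and its adjusted p over all settings ran from 0.00407 to 0.351. The same probe had log2 fold changes of -2.78 at 500 mg/kg and -4.37 at 1000 mg/kg (SE 0.98 each) that did not pass (adjusted p = 0.212 and 0.136). A single probe (1) was higher at 500 mg/kg, and at 1000 mg/kg 3 were higher and 1 was lower. The lower one at 1000 mg/kg also fell at that dose on day 21, by a log2 fold change of -3.77 on day 2 (SE 0.57, adjusted p = 0.0104) and at least 3.83-fold on day 21 (adjusted p = 0.00582), when it was not well above background on any exposed array, and was the only probe called on both days at 1000 mg/kg. No probe was called at more than 1 dose on day 2. At an unadjusted p under 0.05 there were 2518, 2350 and 2169 probes at 100, 500 and 1000 mg/kg.

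With round as a block the day-2 counts at 100, 500 and 1000 mg/kg were 8, 0 and 4, and with scan session as a block 10, 0 and 151. Within round B, with 2 controls, the counts at 100 and 1000 mg/kg were 0 and 0 beside 1936 and 1785 probes at an unadjusted p under 0.05. Round B held 1 exposed array at 500 mg/kg. Within round A, 2 arrays at 500 mg/kg against 1 control gave 0 calls beside 2038. Within scan session 4 there was 1 call at 100 mg/kg and 0 at 1000 mg/kg, the latter beside 2183. Fits of only the arrays compared gave 0 calls at each dose. At 100 mg/kg the count was 737 without control replicate 1, 0 without control replicate 2, 1 without control replicate 3 and 0 without exposed replicate 1 or 2. The count at 500 mg/kg was 241 without control replicate 3, 12 without exposed replicate 3, and 0 without any one of the other arrays. At 1000 mg/kg it was 44 without control replicate 1, and 0, 1 and 2 without exposed replicates 1, 2 and 3.

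Over all 3 doses on day 2, 12 probes differed from control in any exposure and 7 differed among the doses. Of the 12, 6 had a higher mean and 1 a lower mean in all 3 doses, and 6 were also called at a single dose. Of the 7, 6 had their highest or lowest level at 500 mg/kg. When round was a block the counts were 8 and 1, with scan session as a block 6 and 0, and within round B 0 and 0. Fits of only the day-2 arrays gave 0 and 0. For any exposure the count was 907 without replicate 3 at 500 mg/kg and 0 without replicate 2 at 500 mg/kg or replicate 2 at 100 mg/kg. It was 488, 2 and 84 without control replicates 1, 2 and 3, 51 without replicate 3 at 100 mg/kg, and 4, 5 and 3 without replicates 1, 2 and 3 at 1000 mg/kg. For the differences among the doses it was 1703 without replicate 3 at 500 mg/kg and 0 without replicate 1 or 2 at that dose. It was 3, 1 and 143 without replicates 1, 2 and 3 at 100 mg/kg, and 2, 1 and 2 without replicates 1, 2 and 3 at 1000 mg/kg.

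The changes at different doses of the same day were compared across 15507 tested probes, which are not independent replicates. On day 21 the log2 fold changes correlated at r = 0.865 between 100 and 500 mg/kg, 0.636 between 100 and 1000 mg/kg and 0.647 between 500 and 1000 mg/kg. On day 2 the values were 0.358, 0.667 and 0.147. Single arrays moved those of both days. On day 21, leaving out 1 array gave r from 0.737 to 0.938 between 100 and 500 mg/kg. It ran from 0.479 to 0.82 between 100 and 1000 mg/kg and from 0.446 to 0.82 between 500 and 1000 mg/kg. The highest value of each pair came without control replicate 1, in contrasts of round A with round B. On day 2, r between 100 and 500 mg/kg was 0.579 without control replicate 1 and 0.206 without replicate 1 at 500 mg/kg. Between 100 and 1000 mg/kg it was 0.803 without control replicate 1 and 0.432 without replicate 1 at 1000 mg/kg. Between 500 and 1000 mg/kg it was 0.334 and 0.337 without control replicates 1 and 3, and 0.358 and -0.000745 without replicates 2 and 3 at 500 mg/kg. With slide as a fixed block the values of day 2 were 0.938, 0.956 and 0.921. Unchanged groups simulated against the same controls gave a mean r of 0.472, and 95% of 100 draws lay between -0.209 and 0.865. The covariances were 0.558, 0.431 and 0.513 on day 21 and 0.287, 0.528 and 0.102 on day 2, against a simulated mean of 0.228 (95% of draws between -0.0355 and 1.07). The simulation draws arrays without regard to round or replicate number and is the same for both days, so it leaves out the layout of the rounds on day 21. When round was a block the correlations were 0.683, 0.369 and 0.386 on day 21 and 0.494, 0.709 and 0.514 on day 2. Within round A those of day 21 were 0.811, 0.624 and 0.608, and within round B those of day 2 were 0.0955, 0.614 and 0.46.

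With all arrays in one fit, time in un-spiked soil moved more probes than any exposure. Other settings turned this order, and each of those given here has a limit. Array weights, whose estimation stopped before converging, gave 1047 probes for time against 3357 at 500 mg/kg on day 2. No filter gave 385 against 1618 at 1000 mg/kg on day 21. Of the 1618, 1470 were dim probes that were not tested otherwise. Leaving out day-21 control replicate 1 gave 860 for time against 1578 at 500 mg/kg on day 21, the latter in a contrast of round A with round B. Between day 2 and day 21, 1272 probes changed in the controls, 746 higher and 526 lower on day 21, with a median fitted size of 1.70 on the log2 scale (1.49 with dim groups at their bound) and a range at bounds from -5.46 to 7.83. None of the 4 named probes was among them, and the nearest was contig17562 with a log2 fold change of -2.89 (SE 1.01, adjusted p = 0.0851). The median of all tested probes was itself 0.295 higher on day 21, and the balance of directions followed the scaling. With each array's median in place of its 75th percentile 265 probes were higher and 736 lower, with quantile normalization 425 and 628, with the 75th percentile over all probes 167 and 651, and with spike-in scaling 628 and 10. The direction was also read in exposed worms at 500 mg/kg, the one dose with such arrays in round A. Over replicates 1 and 2, 1236 of the 1272 probes (97.2%) moved from day 2 to day 21 in the direction they took in controls, 717 of the 746 and 519 of the 526, against 71.8% of all tested probes and 90.5% of the uncalled ones with an unadjusted p under 0.05. A block of round gave 1948 probes, including all 1272, and with scan session as a block 957 passed. Within round A 127 passed (1 array against 1), within round B 129 passed (2 against 2), and within scan session 4 there were 6 calls. Fitting only the 6 control arrays gave 12 calls, and leaving out day-2 replicate 2 or day-21 replicate 3 gave 642 and 621.

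The test of whether an exposure acted differently on the days gave 12 probes at 1000 mg/kg and 0 at 100 and 500 mg/kg. Of the 12, 5 had a difference above 0 (day-21 change minus day-2 change) and 7 below, 11 had changes of opposite sign on the days, and 8 were also called at 1000 mg/kg on day 21. The difference was at least 6.95 (8.33 as fitted, adjusted p = 0.00210) for GYUW2K401DLQ92, whose day-21 control was not well above background, and 9.30 (SE 1.43, adjusted p = 0.0122) for contig17562. At 100 and 500 mg/kg limma gave 2260 and 498 probes at an unadjusted p under 0.05. The counts at 100, 500 and 1000 mg/kg were 0, 1 and 2 with round as a block and 0, 1 and 7 with scan session as a block, and neither round held all 4 groups at 100 or 1000 mg/kg. Within round A there were 0 calls at 500 mg/kg, and fitting only the 4 groups compared gave 0, 0 and 0. At 1000 mg/kg the count was 1124, 67 and 6 without day-21 control replicates 1, 2 and 3, and 206 and 6 without day-2 control replicates 1 and 3. Leaving out day-21 control replicate 1 makes the day-21 change a contrast of round A with round B. It was 97, 1 and 7 without day-21 exposed replicates 1, 2 and 3, and 1 and 7 without day-2 exposed replicates 2 and 3. At 100 mg/kg it was 259 without day-2 control replicate 1, 54 without day-21 control replicate 1 and 3 without day-2 exposed replicate 3.

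The spike-in controls, which were added when the RNA was labelled, were read against the worm RNA on each array. On day 2 the mean log2 signal of 4 spike-in probes relative to the array's 75th percentile was 1.48 ± 0.54 in controls, 0.74 ± 0.36 at 100 mg/kg, -0.05 ± 0.85 at 500 mg/kg and 0.07 ± 0.36 at 1000 mg/kg (SD, n = 3 each). On day 21 the values were 0.09 ± 1.51, -0.69 ± 0.82, -0.59 ± 0.31 and -1.03 ± 0.73 (SD, n = 3 each). The 4 probes include n11, which also serves to mark the rounds, so the level may differ between rounds for that reason. This was not tested, and each comparison of a dose with control mixes rounds. Over the 12 arrays of day 2 the level fell with dose (Spearman's rho -0.82, two-sided permutation p = 0.00201, adjusted p = 0.0148; Pearson's r -0.644, permutation p = 0.0221, adjusted p = 0.0294). The relation held within the 9 arrays of round B (rho -0.858, exact permutation p = 0.00556, adjusted p = 0.0148; r -0.763, exact permutation p = 0.0177, adjusted p = 0.0283). It also held within the 7 arrays of scan session 4 (rho -0.945, exact permutation p = 0.00952; r -0.879, exact permutation p = 0.00476). Over the 9 exposed arrays of day 21 it did not pass (rho -0.422, exact permutation p = 0.279; r -0.259, exact permutation p = 0.492). Without replicates 1 and 2 at 1000 mg/kg, r was -0.728 over all arrays of day 2 and -0.802 in round B. All 3 arrays of that dose lie equally far from the median dose, and replicate 3 stayed in. The adjustment covers 8 relations.

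**Figure D4:**
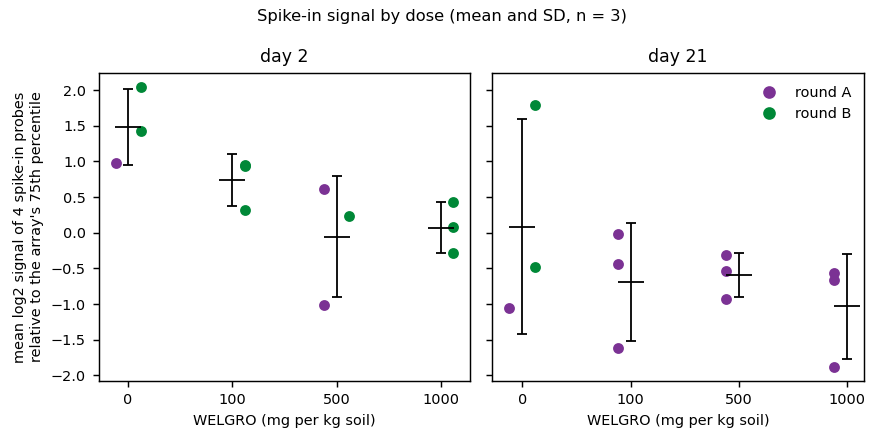
Mean log2 signal of 4 spike-in probes relative to the array's 75th percentile (y axis) by dose (x axis, mg per kg soil) on day 2 and day 21. Points are arrays, purple for round A and green for round B, and bars give the mean and SD of 3 arrays. On day 2 the mean went from 1.48 in controls to 0.07 at 1000 mg/kg.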

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

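Of the tests in this part, the block of the round and the counts over splits that part or keep the day-21 pairs were chosen only after the result was seen. The fitted change at 1000 mg/kg differed between day 21 and day 2 in 12 probes, by limma's test of the difference between the days. At this dose every exposed array of day 2 was of round B and every one of day 21 of round A. The difference between the days thus also holds a difference of round. Among the named probes the difference of log2 fold changes was 8.33 as fitted for GYUW2K401DLQ92 (at least 6.95, since its day-21 control was not well above background) and 9.30 for contig17562, both risen on day 21 and called on that day only. When exposed and control arrays were reassigned within each day, 7 of 100 splits gave 12 or more probes, the real one included, and the highest other gave 89, so chance was not excluded for this count. Among the 31 of these splits that part all 3 day-21 pairs, 3 gave 12 or more and the highest other gave 36. The split with 89 calls set day-21 control replicates 1 and 3 with exposed replicate 1. A block of round left 2 probes, 1 of them among the 12. At 100 and 500 mg/kg the real count was 0, which all 100 splits reached, and the highest other splits gave 10 and 4722. The split with 4722 calls set both round-B controls and the round-B exposed array of day 2 together, and so follows the round on that day.

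For the 42 probes at 1000 mg/kg on day 21, 2 of the 10 splits of the 6 arrays gave as many calls, the real one included, and the highest other gave 70, with control replicates 1 and 3 and exposed replicate 1 on one side. With 10 splits no share under 0.05 can be reached. Of the 4 splits that part all 3 replicate pairs, the real one gave 42 and the others 0. For these 42 probes, the labelling and scan round as the whole cause is argued against by the size of the change with round as a block. The median of the 42 fitted changes stayed at 101% of its value (2.73 without and 2.76 with the block, lower quartile 2.03, SE 0.47 and 0.51), although 17 lost their call, their median going from 2.02 (SE 0.35) to 1.70 (SE 0.39). This is weak evidence, since the 42 were called with round in the spread, which favours probes that differ little by round. With scan session as a block 13 of the 42 stayed called. Noise on the control arrays with wide negative controls stays open. On all arrays, 35.7% of the 42 probes (15, Wilson 95% interval 23.0% to 50.8%) were well above background, against 47.7% of all tested probes, but a probe that rises out of background or falls into it lowers this share by itself, so the share decides nothing. An effect of the exposure, which the design names, remains a candidate explanation that these arrays do not separate from that noise, nor fully from the round.

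For the 1272 probes that changed with time in controls, 1 of the 10 splits, the real one, gave as many, and the highest other gave 595, with the 3 controls of narrow negative-control spread on one side. No share under 0.05 can be reached with 10 splits. Each of the 2 control groups held 1 array of round A and 2 of round B, so an equal shift between the rounds cancels in this contrast. The round as the whole cause is also argued against by day effects measured inside each round. The effect in control replicate 2 (both arrays in round B) correlated across probes with that of replicates 1 and 2 at 500 mg/kg (all in round A) at 0.518 and 0.445, above the 0.3 fixed before the value was seen. Of the 1272, 53.6% (682, Wilson 95% interval 50.9% to 56.3%, which takes the probes as independent) were well above background on all arrays, against 47.7% of all tested probes. The called probes are thus not mainly dim ones. Noise of the arrays with wide negative controls stays open, since the split with 595 calls follows that spread. It follows the scan session as closely, since the 3 controls of narrow spread are also the controls of scan session 4. This split thus cannot tell noise from scan session. A change of the worms with time in soil is a hypothesis that remains, found and tested on the same arrays, and age and the condition of the soil were not told apart.

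For the other counts, the splits were as follows. At 100 mg/kg on day 2, 2 of 10 splits reached the real count of 3 and the highest other gave 50. At 500 mg/kg on day 2, 2 of 10 reached the count of 1 and the highest other gave 2340, the split that sets all 3 arrays of round B against all 3 of round A, which points to a structure of the arrays. At 1000 mg/kg on day 2 the real split alone gave 4 and the highest other 0. At 100 mg/kg on day 21 all 10 splits reached 0 and the highest other gave 1, and at 500 mg/kg on day 21 the real split alone gave 5 and the highest other 0. With 10 splits none of these can reach a share under 0.05. Over 100 drawn splits, 3 reached the 12 probes of any exposure on day 2 (highest other 263), 3 reached the 36 of day 21 (highest other 105), 3 reached the 7 that differed among the doses on day 2 (highest other 8), and 1, the real one, reached the 40 of day 21 (highest other 20). For an assignment by chance that ignores the round and the replicate numbers, the share was thus under 0.05 for these 4 counts. It rests on 100 drawn splits and was not adjusted over the counts tested, so chance is not excluded by it. When labels of day 21 were reassigned only within each replicate number, the real split alone reached its count, for any exposure among 100 drawn splits (highest other 31) and among the doses in all 36 splits (highest other 16). Only the arrays compared among the doses on day 21 all lie in 1 round, so for the other 3 counts the round remains a possible source of the small share. With round as a block the day-2 count among the doses was 1. Any exposure then gave 8 probes on day 2, 6 of the 12 among them, and 41 on day 21, 33 of the 36 among them. The splits with 263 and 105 calls show that some other assignments call several times as many.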

How the results depend on the processing

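Settings added only after seeing the data were normexp on median signals, the 75th percentile over all probes, spike-in scaling, slide as a random block, the round as a block with or without the replicate number, and fits without the 4 arrays of widest negative controls or within a round or session. Counts of called probes follow in this order: 100, 500 and 1000 mg/kg on day 2, the same doses on day 21, any exposure on day 2 and day 21, differences among the doses on day 2 and day 21, day 21 against day 2 in controls, and the difference between days at 100, 500 and 1000 mg/kg. As reported they were 3, 1, 4, 0, 5, 42, 12, 36, 7, 40, 1272, 0, 0 and 12. Over the settings other than single left-out arrays, 116 of 283 counts stayed within 1.5 times of these and 167 did not. The 116 include counts that could not move, those of the series-wide values and of the F-tests under the 2-fold minimum. Where no cause is given, the cause was not tested.

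With quantile normalization the counts were 17, 18, 45, 0, 6, 54, 57, 34, 5, 20, 1053, 0, 1 and 26. With median scaling they were 3, 0, 6, 0, 3, 28, 15, 39, 12, 42, 1001, 0, 1 and 19. With no filter they were 1, 0, 2, 0, 18, 1618, 0, 48, 1, 23, 385, 0, 0 and 5. Of the 1618, 1470 lay outside the 15565 probes tested otherwise and all 1470 were lower at 1000 mg/kg, so they come from dim probes. With the strict filter, which tests 7428 probes, they were 3, 0, 5, 0, 2, 23, 5, 13, 0, 5, 942, 2, 2 and 7. The series-wide values are the same numbers and gave the same counts. With only the arrays compared they were 0, 0, 0, 0, 0, 0, 0, 21, 0, 12, 12, 0, 0 and 0, where fewer arrays inform the spread. With slide as a fixed block they were 3 for any exposure and 3 among the doses on day 2 and 0 otherwise, with 5 residual degrees of freedom left. With scan session as a block they were 10, 0, 151, 0, 2, 21, 6, 61, 0, 74, 957, 0, 1 and 7. With array weights they were 1386, 3357, 1867, 374, 3216, 1330, 7264, 2267, 8999, 1616, 1047, 517, 3 and 1897, with weights from 0.247 to 12.6 whose estimation stopped before converging. With a trended and robust prior they were 4, 0, 4, 0, 5, 39, 11, 39, 1, 44, 1263, 0, 2 and 20. A minimum of 2-fold, which does not enter the F-tests over several doses, changed only the control count, to 1204.

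With the replicate block they were 958, 3, 35, 0, 7, 80, 767, 65, 125, 62, 2195, 12, 0 and 90. On day 21, where the numbers pair the arrays, the replicate block changed no other call by over 1.5 times than those given beside the results. On day 2 and for time in controls the numbers do not pair the arrays by the rule used for day 21 (correlations of replicates 1, 2 and 3 of 0.072, -0.44 and 0.35 at 100 mg/kg, 0.4, -0.5 and -0.31 at 500 mg/kg, 0.69, 0.081 and 0.21 at 1000 mg/kg, and 0.12, 0.39 and -0.22 for time). There 2, 2, 3 and 1 of 6 arrays correlated best with their own number. Over the arrays of both days together, the number explained 50.8% of the second principal component.

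With normexp on median signals and quantile normalization the counts were 34, 0, 36, 0, 6, 64, 21, 33, 3, 18, 1059, 1, 2 and 18. With the 75th percentile over all probes they were 2, 0, 9, 0, 2, 36, 13, 45, 6, 43, 818, 0, 0 and 15. With spike-in scaling they were 0, 0, 0, 0, 2, 17, 0, 15, 0, 1, 638, 0, 0 and 2. With slide as a random block (correlation 0.358) they were 1, 0, 4, 0, 5, 38, 5, 61, 4, 61, 785, 0, 0 and 1. With round as a block they were 8, 0, 4, 0, 3, 33, 8, 41, 1, 60, 1948, 0, 1 and 2, and with round and replicate block together 1894, 6, 21, 0, 5, 48, 328, 72, 1, 99, 3519, 0, 2 and 5. Without the 4 arrays of widest negative controls they were 0, 1564, 0, 413, 1436, 662, 1527, 224, 1712, 43, 116, 0, 1 and 0. That setting leaves only round-B controls, and of the day-21 controls only replicate 2. On day 21 it thus compares round A with a single array of round B, and the spread comes from other groups. Within round A the counts that could be had were 0 at 500 mg/kg on day 2, 0, 2 and 12 on day 21, 24 for any exposure and 38 among the doses on day 21, 127 for controls and 0 for the difference between days at 500 mg/kg. Within round B, with 1 array at 500 mg/kg, they were 0 and 0 at 100 and 1000 mg/kg on day 2, 0 and 0 for any exposure and among the doses, and 129 for controls. Within session 4 they were 1 and 0 at 100 and 1000 mg/kg on day 2 and 6 for controls. Counts of 0 stood beside 164 to 7834 probes at an unadjusted p under 0.05.

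Leaving out 1 array moved 72 of 120 counts by over 1.5 times. The lowest and highest were 0 and 737, 0 and 241, 0 and 44, 0 and 745, 1 and 1578, 16 and 1204, 0 and 907, 23 and 480, 0 and 1703, 16 and 195, 621 and 1376, 0 and 259, 0 and 0, and 1 and 1124. Of these, 745, 1578, 1204, 480 and 1124 come from leaving out day-21 control replicate 1, the only day-21 control of round A. Spike-in scaling moved the median of all tested probes up by 0.67 to 1.53 in the exposure contrasts and 1.39 in controls over time, and median scaling moved it by -0.13 to -0.45. In the controls over time the 75th percentile over all probes moved it by -0.45 and quantile normalization by -0.22. The directions at 1000 mg/kg on day 21 were 28 higher and 14 lower as reported, 46 and 8 with quantile normalization, 15 and 2 with spike-in scaling, 88 and 1530 with no filter, 56 and 91 without exposed replicate 1, and 29 and 28 without control replicate 2. No setting turned the direction of a named probe. The series-wide values and the 2-fold minimum are among the settings counted next, and both leave the fit unchanged. GYUW2K401DLQ92 stayed called in 23 of 25 settings (log2 fold change 5.70 to 10.10), contig17562 in 22 of 25 (5.82 to 9.81), contig14152 in 18 of 25 (-7.53 to -2.95) and contig24256 in 16 of 27 (-7.36 to -5.24). The adjusted p reached 1, 1, 1 and 0.351 in these. Not run were normexp on mean signals, for which the median signals stood in, and every setting of the gene lists, which need gene names. At most 43.6% of the probes rose above background on an array, which limits what the filter can test.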

Other observations

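The test in this part was chosen only after the result was seen. On day 2 the spike-in signal relative to the worm RNA was lower at higher doses. The labelling and scan round as the cause is argued against by the order within the arrays of round B alone (Spearman's rho -0.858, exact two-sided permutation p = 0.00556). A hypothesis is that exposed worms yielded more amplifiable messenger RNA per ng of total RNA after 2 days. Differences in RNA quality or in the amount of RNA or spike-in put into the labelling may give the same order and were not tested. Spike-in scaling would keep such a difference. With it, the day-2 median log2 fold change of all tested probes was 0.81, 1.84 and 1.47 at 100, 500 and 1000 mg/kg against control. It called 0 probes at each dose. The probes used for scaling include n11, which also marks the rounds, and each of these contrasts mixes rounds. These medians may thus hold a difference of round.

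The changes at a given dose on day 2 and day 21 correlated across probes at -0.142 for 100 mg/kg, 0.572 for 500 mg/kg and -0.25 for 1000 mg/kg. At 500 mg/kg 2 of the 3 exposed arrays of day 2 belonged to round A, as all exposed arrays of day 21 did, and at the other doses none did. Beside a block of round the correlations were -0.39, 0.101 and -0.109.

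Probes designed on single reads were seen more often than probes on contigs. The median over arrays of the share well above background was 35.6% for reads and 29.4% for contigs, and 18.3% and 15.8% were above background on all arrays.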
